A study of Mus musculus with 4 samples.

How the data were processed

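Livers and spleens of mice on 2 diets were profiled on Agilent whole mouse genome arrays with 2 colours. Per the labels, total RNA was extracted with a kit, pooled per diet and tissue, and labelled with Cy3 or Cy5. The 4 arrays lie on 1 slide, so slide effects could not be examined as batches. Array 1 of each tissue holds the NP pool in Cy5 and array 2 holds it in Cy3, per the labels.

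The deposited scanner files give the intensity of each spot as mean foreground and median local background signals in both dyes, together with flags for spots well above background, saturated or not uniform, per the file headers from Agilent Feature Extraction, version 9.5.3.1 in the submitters' processing notes. The same deposited files hold the software's processed intensity per dye and its log10 ratio of Cy5 over Cy3, per the file headers. They also hold a p-value of that ratio, which measures spot error only, per the file headers. The deposited value table of the series holds log10 ratios whose making is not given in the sources used here. Set against the scanner files, its columns correlated with the scanner log10 ratio at -0.992, 0.990, -0.989 and 0.998, which gives low NP over NP in every column. Its scale is that of the scanner ratio, rounded. Between 2.69% and 22.6% of its features differed from it beyond rounding, and its column medians were 0.03 and -0.07 for liver and -0.01 and -0.04 for spleen, so the columns are not centred on 0. The origin of the differing features stays unknown.

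A few lines of the scanner files end in a lone carriage return and were split before reading. Each array held 45018 spots, of which 1639 were controls. In limma 3.58.1 under R 4.3.3, the background of the mean signals was corrected with normexp and an offset of 50, and log ratios were normalized within each array by loess, with control spots and spots flagged as outliers given no weight. Between 109 and 180 spots per array were flagged as outliers and left out. Signs were turned to NP over low NP, and replicate spots of a probe were averaged. The 245 probes spotted repeatedly had a within-array SD of log2 ratios between 0.0244 and 0.0656. Tables were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

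Probes were named through a table of mouse RefSeq genes of assembly GRCm38.p6, used for names only. Of 41174 probes, 22951 matched by accession, 6659 by symbol and 3109 by an unambiguous synonym, and 8455 kept the name in the file, which gave 27670 gene labels. Probe positions are those of the array files, in mm7. Where a gene had several probes, the brightest over all 4 arrays was used. Of 5830 liver genes with several measured probes, 225 had a called probe and 156 of these also had a probe that was not called. In spleen the numbers were 6435, 416 and 249. No gene had probes called in opposite directions.

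A gene was measured in a tissue when its probe was well above background in at least 1 channel on both arrays. It was called when both arrays showed at least 1.5-fold in the same direction. The arrays of a tissue were treated as a dye swap of the same pools, so no test was run, and the number of genes past 1.5-fold in opposite directions is given as a measure of error. The labels number the pooled samples 1 and 2 in step with the dye orientation, so pools of their own on each array are not excluded. The 40 gene lists, the rule for named genes and the alternatives listed first below were fixed before the data were examined. Lists were described by the median log2 ratio of their measured genes and its percentile among 10000 random lists of the same size, matched on mean intensity in 10 bins. A list stood apart outside the central 95% with the same sign on each array. For genes not well above background in one diet's channel on both arrays, the bound sets the bright pool against the higher of the lowest signal of probes well above background and the probe's own, per channel after loess and Aquantile. These bounds are open to dye bias, balanced here by the swap.

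The named genes are, per tissue, the 10 higher and 10 lower recognised genes, well above background in both channels on both arrays and called, with the largest value of the smaller of the 2 arrays' absolute ratios, the 3 largest bounds, up to 4 members of each list that stood apart or held at least 3 called genes, up to 10 genes called in both tissues, and 9 genes of nucleotide metabolism and of the tissues themselves. The text names some of the members that the rule allows, and a few genes that the rule takes are not reported here.

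The same calls were tested on simulated dye swaps. The noise SD was a robust estimate from the difference between a tissue's 2 arrays over brighter probes, scaled to 1 array (0.227 in liver, 0.165 in spleen). Noise was drawn separately for each dye and averaged in the ratio. The simulated ratios were thus less noisy than the data, so the recovery and the false calls below are likely too favourable. Over 41145 liver probes, 34% of 1.5-fold changes and all 2-fold, 3-fold and 4-fold changes were recovered, and 71 unchanged probes were called. Over 41172 spleen probes, 26% of 1.5-fold and all larger changes were recovered, and 0 unchanged probes were called. With 1000 bright genes set 16-fold lower, the recovery of 1.5-fold changes was 36% in liver and 20% in spleen. Over the 16967 liver genes, 7% of 200 unchanged simulated lists of 20 genes stood apart, and of 50 lists shifted by 0.3 on the log2 scale, all did.

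The alternatives were the scanner software's processed signals, the deposited value table, no background correction, an offset of 0, median centring, no filter or a stricter filter on dim probes, the mean of a gene's probes, a spot error p under 0.01, each array left out in turn, thresholds of 2-fold and 1.3-fold, a rule on the mean of both arrays, and random lists not matched on intensity. After the data were seen, 2 were added, negative controls as background and leaving out genes at least 2-fold higher in the other tissue.

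The share of the other tissue's signal in a low-NP pool was estimated for genes at least 16-fold higher in the NP pool of the other tissue. It is the low-NP signal minus the NP signal, divided by the other tissue's signal minus the NP signal, all in the same dye. The estimate was made in each dye against each of the other tissue's pools, which gives 4 estimates per tissue.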

Results

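Gene expression was measured in the liver and spleen of male C57BL/6J mice, 13 weeks old, that had been fed for 4 weeks either a purified diet low in nucleoprotein (low NP, 0.03% nucleic acids) or the same diet with 1.2% nucleoprotein added (NP, 0.5% nucleic acids). RNA had been pooled per diet and tissue before labelling, and the labels do not give the number of mice in a pool. Each tissue was hybridised on 2 arrays of 1 slide, with the NP pool in Cy5 on array 1 and in Cy3 on array 2. These 2 arrays were treated as a dye swap of the same 2 pools, which makes 1 replicate per diet and tissue, so no test of the diet was run and no p-value is given. The labels number the pooled samples 1 and 2 along with the dye orientation, and do not settle whether each array held pools of its own. Values are log2 ratios of NP over low NP, averaged over the 2 arrays. The value after ± is the distance of each array's value from the mean of the 2 arrays. A list's value is the median of its genes' means, and its ± is the distance of the list's medians on each array from their own mean, so the array medians need not lie evenly around the value. The ± covers technical error, and would also hold the spread of pools if each array had its own. This direction is opposite to that of the series' deposited value table, which holds low NP over NP. A gene was called higher or lower when it differed at least 1.5-fold in the same direction on both arrays. Each array carried 41174 probes, and between 58.6% and 94.7% of them were well above background, depending on array and dye. The highest shares were those of spleen array 1, at 93.1% in Cy3 and 94.7% in Cy5, where the median negative-control signal was 156 in Cy3 and 307 in Cy5, against 62.7 and 71.9 on spleen array 2. The precision is limited by the number of arrays.

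The genes fixed as checks of the labels separated the tissues in the NP pools. Apoa1, an apolipoprotein made by hepatocytes, had a normalized log2 signal of 16.9 in NP liver and 10.2 in NP spleen. Cd79b, a part of the B cell receptor, had 9.63 in NP liver and 16.6 in NP spleen. In the low-NP pools the tissues lay closer together. Apoa1 was at 15.5 in low-NP spleen, and Cd79b was at 14.2 in low-NP liver. The albumin gene Alb, with saturated spots, was at 14.0 in NP spleen (15.1 on array 1 and 12.9 on array 2) and between 17.9 and 18.9 in the other pools, which saturation keeps from being ranked.

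**Figure D1:**
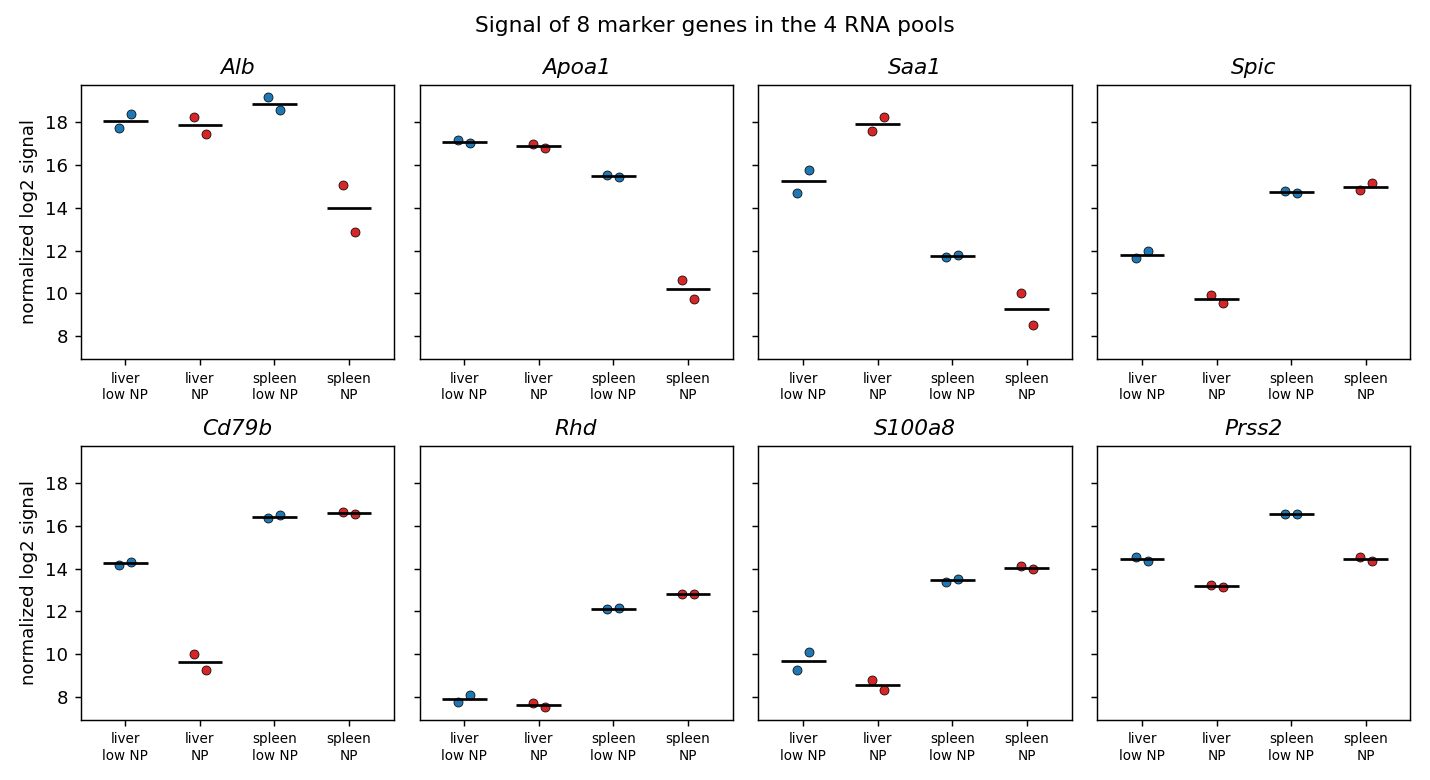
Normalized log2 signal (vertical axes) of 8 marker genes in the 4 RNA pools (horizontal axes), with low NP in blue, NP in red, points for the 2 arrays and bars for their mean. Apoa1 was at 15.5 in low-NP spleen and 10.2 in NP spleen, and Cd79b at 14.2 in low-NP liver and 9.63 in NP liver.

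The first comparison asked which liver transcripts differed between the pool of mice fed added nucleoprotein and the low-NP pool. In liver, genes of lymphocytes were lower in the NP pool and a small group of acute-phase genes was higher. Of 16967 measured genes, 12 were called higher and 620 lower, and 41 genes passed 1.5-fold on both arrays in opposite directions, following the dye. The recognised genes that ranked highest were Saa1 (2.67 ± 0.22), Saa2 (2.65 ± 0.38) and Saa3 (2.65 ± 0.22), which encode serum amyloid A proteins, and Orm3 (2.59 ± 0.47), an orosomucoid. The metallothionein genes Mt2 (1.72 ± 0.17) and Mt1 (1.44 ± 0.05) followed, then Lcn2 (1.15 ± 0.54), which encodes the iron-siderophore binding protein lipocalin 2, and Dnajc12 (1.05 ± 0.08). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 0.75 ± 0.01 and Mid1ip1 0.72 ± 0.12. The Saa1 probe lies on chromosome 7 at 42916901 to 42916960 and the Cyp7a1 probe on chromosome 4 at 6193456 to 6193515, in the mm7 coordinates of the array files.

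The 10 recognised genes that ranked lowest in liver were mostly those of B cells and plasma cells. They were the immunoglobulin genes Iglv1 (-5.22 ± 0.48) and Ighm (-4.56 ± 0.35), Ms4a1 (-4.66 ± 0.70), which encodes CD20, and Cd79b (-4.62 ± 0.43, probe on chromosome 11 at 106420507 to 106420566). Pou2af1, a coactivator of B cells, was -4.27 ± 0.65, and Fcmr, the IgM Fc receptor, was -3.84 ± 0.74. Jchain, the joining chain of polymeric immunoglobulin, was -3.65 ± 0.51. Ly6d (-3.53 ± 0.35), Ltb (-3.52 ± 0.29) and S100a4 (-3.40 ± 0.30) completed the group. A further 9 genes called lower had probes that were not well above background in the NP channel on either array, so only a bound can be given. Coch was at least 10.7-fold lower, Bcl11a at least 3.76-fold and Btla at least 3.21-fold, from normalized levels per channel.

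Of the 40 gene lists, 22 stood apart from random lists of matched intensity in liver, 15 below and 7 above. Lists of immune cells were lower in the NP pool. The B cell list had a median of -2.13 ± 0.75 with 16 of 20 measured genes called lower, and the T cell list -1.46 ± 0.74 with 13 of 23, including Cd8b1 (-3.54 ± 0.74) and Cd3d (-2.56 ± 0.65). The median was -0.97 ± 0.33 for antigen presentation (12 of 21 called lower, array medians -0.83 and -1.50), with H2-Ab1 at -2.43 ± 0.19 and Cd74 at -2.40 ± 0.00. It was -0.65 ± 0.23 for plasma cells (5 of 15, array medians -0.28 and -0.73), with Mzb1 at -3.36 ± 0.65, and -0.64 ± 0.38 for natural killer and cytotoxic cells (6 of 17), with Ccl5 at -2.81 ± 0.28. Macrophages and monocytes were at -0.53 ± 0.12 (8 of 26), with Vcam1 at -2.32 ± 0.20 and Spic, a transcription factor of splenic red pulp macrophages, at -2.08 ± 0.34. Cytokines and chemokines were at -0.35 ± 0.31 (4 of 24), with Ccl19 at -2.99 ± 0.40, and dendritic cells at -0.36 ± 0.26 (1 of 12), with Itgax at -1.56 ± 0.59. Granulocytes were at -0.27 ± 0.19, with S100a9 called lower (-1.94 ± 0.21) and Lcn2 called higher among 14 measured genes. Megakaryocytes and platelets were at -0.23 ± 0.15 (4 of 15), with Ppbp at -1.78 ± 0.74. Without the genes at least 2-fold higher in the NP spleen pool than in the low-NP liver pool, antigen presentation (-0.29, 0 of 6 remaining genes called) and plasma cells (-0.11, 1 of 9 called lower) still stood apart. The 1 plasma cell gene still called was Creld2 (-0.65), which is also in the heat shock list. Of the 9 remaining plasma cell genes, 4 lay above 0, so this result is not particular to plasma cells. T cells (-0.059), dendritic cells (-0.073), megakaryocytes (-0.11), macrophages (0.025), cytokines (0.016) and granulocytes (0.11) then did not, the last 3 with medians above 0, and too few genes were left for a median of B cells and natural killer cells.

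Transcripts of the exocrine pancreas were lower in NP liver as well, with a median of -0.97 ± 0.01 and 20 of 24 measured genes called lower. Among them were Reg2 (-2.42 ± 0.55), the trypsinogen gene Prss2 (-1.26 ± 0.07) and the amylase gene Amy2 (-1.24 ± 0.01). Ribosomal protein genes had a median of -0.64 ± 0.14, with 5 of 27 called lower, Rps14 (-0.82 ± 0.23) among them, and 0 above 0. The ribosomal and respiratory chain lists were included as lists of RNA quality. A difference in RNA quality between the pools was not tested further. Cell cycle genes were at -0.57 ± 0.35 (5 of 33), with Mki67 at -2.03 ± 0.57, immediate early genes at -0.22 ± 0.11 (4 of 22), with Ier5 at -1.61 ± 0.17, and endothelial and stromal genes at -0.24 ± 0.18 (2 of 21), with Col1a2 at -0.96 ± 0.21. Cell cycle (-0.12), immediate early (-0.092) and endothelial genes (0.14) did not stand apart without the genes of the other tissue, and pancreas (-0.97, 20 of 24 called lower) and ribosomal genes (-0.69, 3 of 18) did.

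The medians of 5 metabolic lists, the acute-phase list and the circadian clock list lay slightly higher in the NP pool, mostly without called genes. Cholesterol synthesis had a median of 0.29 ± 0.01, with 24 of 25 genes above 0 and none called. Its highest members were Dhcr7 (0.51 ± 0.22) and Idi1 (0.47 ± 0.15). Fatty acid synthesis was at 0.26 ± 0.00, with 20 of 21 genes above 0 and 1 called lower, and its highest members were Fasn (0.59 ± 0.47) and Srebf1 (0.52 ± 0.08), neither called. The acute-phase list was at 0.29 ± 0.07 with 5 of 27 genes called higher, and its array medians, 0.53 and 0.39, were both above that value. The circadian clock list was at 0.13 ± 0.01 (Hlf, 0.32 ± 0.14, not called) and bile acid synthesis and transport at 0.12 ± 0.03 (array medians 0.20 and 0.14, Cyp7a1 called, Abcg5 0.40 ± 0.04 not called). Xenobiotic metabolism was at 0.08 ± 0.00 (Sult1c2, 0.53 ± 0.09, not called) and urea cycle and amino acid breakdown at 0.08 ± 0.11 (Prodh, 0.51 ± 0.01, not called), but the first did not stand apart with the scanner software's processed signals (0.13) nor the second on array 1 alone (0.024). Median centring in place of loess moved the median of all liver genes to 0.06. Dilution of liver RNA in the low-NP pool was not tested as a source of the metabolic and clock medians. Spleen genes at least 16-fold higher in NP spleen reached median shares between 12.2% and 19.1% in that pool. These small medians thus do not separate dilution from a metabolic difference.

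The lists of nucleotide metabolism did not stand apart in liver. The medians were 0.04 ± 0.08 for purine breakdown and salvage, 0.01 ± 0.00 for de novo purine synthesis and 0.08 ± 0.01 for pyrimidine metabolism, with 0 genes called in each. The nucleoside transporter list was at -0.02 ± 0.02 with 1 of 6 called lower, and nucleases and nucleic acid sensors at -0.02 ± 0.08 with 2 of 23 called lower. Xdh, which encodes xanthine dehydrogenase, was 0.15 ± 0.20, the urate oxidase gene Uox 0.04 ± 0.52, Ppat 0.20 ± 0.12, Cad -0.37 ± 0.03 and the nucleoside transporter gene Slc29a1 0.17 ± 0.11, none of them called. Of the genes fixed as label checks, Alb (-0.19 ± 0.71) and Apoa1 (-0.21 ± 0.02) were not called. The other lists that did not stand apart were fatty acid oxidation (0.02 ± 0.03, 0 called), oxidative stress (0.01 ± 0.08, with Mt1 and Mt2 called higher and 1 gene lower), amino acid stress (0.04 ± 0.01, 1 lower), glucose production (0.02 ± 0.07, 0 called) and sex-biased liver genes (-0.03 ± 0.09, 0 called). Interferon response (-0.05 ± 0.10, 1 lower), erythroid cells (-0.06 ± 0.05, 2 lower), hepatocytes (0.02 ± 0.42, 0 called), bile duct (0.07 ± 0.04, 0 called), adipocytes (0.07 ± 0.04, 0 called) and muscle (-0.12 ± 0.14, 0 called) did not stand apart either, nor did heat shock (-0.13 ± 0.10, 1 lower) and the respiratory chain (-0.02 ± 0.07, 0 called). Without the genes of the other tissue, erythroid cells (0.16, 0 of 7 called) and heat shock (-0.12, 1 of 23 called lower) stood apart.

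Of the 620 genes called lower in liver, 566 were at least 2-fold higher in the NP spleen pool than in the low-NP liver pool, which is 91.3%, against 14.4% of the other measured genes. At least 4-fold, the shares were 71.6% and 1.99%. Without the genes at least 2-fold higher in the other tissue, 54 were called lower and 12 higher. Array 1 alone gave 345 genes higher and 700 lower, array 2 alone 86 and 1941, and leaving out the background correction gave 1328 lower. The scanner software's processed signals gave 297 higher and 1745 lower, against 12 and 620 here.

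**Figure D2:**
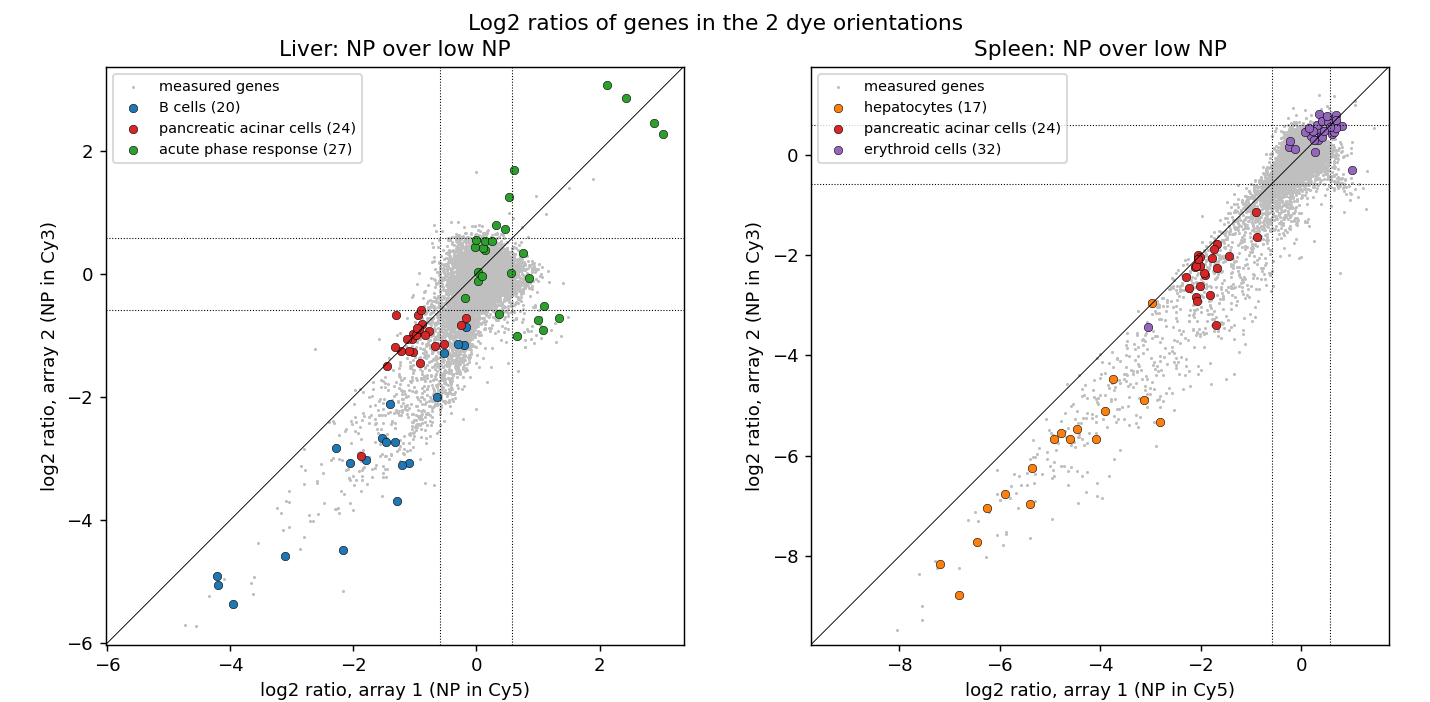
Log2 ratio of NP over low NP on array 1 (horizontal axes, NP in Cy5) against array 2 (vertical axes, NP in Cy3) in liver and spleen (grey, measured genes; coloured, members of the named lists with their number in brackets; dotted lines, 1.5-fold; diagonal, equal values). B cell genes in liver and hepatocyte genes in spleen lay far below 0 on both arrays (list medians -2.13 and -5.17).

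The second comparison asked the same of the spleen. In spleen, transcripts of hepatocytes and of the exocrine pancreas were lower in the NP pool. The median of the erythroid list lay slightly above 0, with 3 of 32 measured genes called higher and 1 lower. Of 18409 measured genes, 8 were called higher and 1170 lower, and 25 passed 1.5-fold in opposite directions. The 5 recognised genes called higher were Hemgn (0.74 ± 0.05), Redrum (0.73 ± 0.12), Rhd (0.69 ± 0.00), Ank1 (0.67 ± 0.03) and Ctse (0.65 ± 0.01). Rhd encodes a blood group protein and Ank1 the red cell ankyrin. The Rhd probe lies on chromosome 4 at 134274540 to 134274599 in mm7. The recognised genes that ranked lowest were genes of the liver. Akr1c6 was -8.75 ± 0.71 (probe on chromosome 13 at 4341660 to 4341719 in mm7), Fabp1, the liver fatty acid binding protein, -8.41 ± 0.86, and the fibrinogen gene Fgg -7.98 ± 0.38. Mup1 (-7.84 ± 0.96) and Mup5 (-7.74 ± 0.49) encode major urinary proteins, and some Mup1 spots were saturated. Ambp (-7.80 ± 0.98), Aadac (-7.70 ± 0.41), Apoh (-7.67 ± 0.48) and Rgn (-7.52 ± 0.71) were also among them. For 11 genes called lower the probe was not well above background in the NP channel on either array. Slc2a2 was at least 37.4-fold lower, Spp2 at least 35.7-fold and Ugt2b35 at least 15.3-fold.

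In spleen 31 lists stood apart, 17 below and 14 above. The hepatocyte list had a median of -5.17 ± 0.44 with all 17 measured genes called lower, among them Cps1 (-7.09 ± 0.64) and Rbp4 (-6.65 ± 0.39). Apoa1 was -5.29 ± 0.37 and Alb, with saturated spots, -4.87 ± 0.79. Lists of hepatic metabolism lay at -4.11 ± 0.46 for sex-biased liver genes (14 of 18 called lower, Mup3 at -5.25 ± 0.23), -3.42 ± 0.63 for bile acid synthesis and transport (14 of 18, Slco1b2 at -7.08 ± 0.60) and -3.34 ± 0.44 for urea cycle and amino acid breakdown (22 of 26, Otc at -6.01 ± 0.39). Xenobiotic metabolism was at -2.50 ± 0.41 (30 of 37, Cyp2e1 at -5.17 ± 0.38) and the acute-phase list at -2.37 ± 0.55 (23 of 28, Hpx at -6.41 ± 0.35). Glucose production was at -1.49 ± 0.38 (10 of 17, Fbp1 at -6.86 ± 0.44), fatty acid synthesis at -1.39 ± 0.27 (14 of 21, Dgat2 at -3.43 ± 0.16), fatty acid oxidation at -1.08 ± 0.00 (21 of 30, Cyp4a14 at -2.48 ± 0.90) and cholesterol synthesis at -1.04 ± 0.15 (18 of 25, Tm7sf2 at -3.27 ± 0.22). The circadian clock list was at -0.41 ± 0.02 (4 of 19, Hlf at -1.06 ± 0.45), oxidative stress at -0.34 ± 0.14 (5 of 20, Cat at -2.07 ± 0.05), the respiratory chain, a list of RNA quality, at -0.36 ± 0.04 (0 of 28 called and 0 above 0), heat shock at -0.29 ± 0.01 (1 of 24, Hyou1 at -0.66 ± 0.04, on array 2 alone -0.28 and not apart), plasma cells at -0.26 ± 0.03 (2 of 15, Sdc1 at -1.01 ± 0.02) and bile duct at -0.26 ± 0.15 (4 of 10, Krt8 at -4.00 ± 0.47). In low-NP spleen, 4 bile duct genes at least 16-fold higher in NP liver had median shares of the liver signal between 21.0% and 27.0%. The exocrine pancreas list was at -2.11 ± 0.10, with all 24 measured genes called lower and Cpb1 at -2.50 ± 0.43.

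Most lists of blood and immune cells, but not plasma cells, lay slightly above 0 in spleen. Dilution of spleen RNA in the low-NP pool was not tested as a source of these values. The erythroid list had a median of 0.40 ± 0.05, with 3 of 32 genes called higher, 1 called lower and 29 above 0, and its highest member beside the called ones was Eraf (0.69 ± 0.13). Granulocytes were at 0.26 ± 0.06 with 0 of 22 called (Chil3, 0.74 ± 0.19). With loess, megakaryocytes were at 0.22 ± 0.09, cell cycle genes at 0.20 ± 0.01, B cells at 0.16 ± 0.02, antigen presentation at 0.14 ± 0.03, macrophages at 0.13 ± 0.02, interferon response at 0.11 ± 0.01, natural killer cells at 0.10 ± 0.01, T cells and dendritic cells each at 0.08 and endothelial genes at 0.06 ± 0.01, but with median centring, which moved the median of all spleen genes from -0.02 to -0.15, these 10 medians were below 0. No gene of these 10 lists was called higher, and 4 of 21 endothelial, 2 of 26 macrophage, 1 of 25 T cell and 1 of 35 interferon genes were called lower. The array medians were 0.085 and 0.12 for B cells, 0.074 and 0.14 for antigen presentation, and 0.025 and 0.023 for T cells, which did not stand apart on either array alone. Members of those lists included Mki67 (0.38 ± 0.02), Rsad2 (0.39 ± 0.03), Ccr2 (0.45 ± 0.09), Itga2b (0.37 ± 0.24), Pax5 (0.24 ± 0.06), H2-Ab1 (0.23 ± 0.34), Klrd1 (0.24 ± 0.03) and Lat (0.22 ± 0.07), none of them called. The label check Cd79b (0.17 ± 0.10) was not called either. Nucleoside transporters (0.12 ± 0.01, Slc29a3 0.26 ± 0.20) and muscle genes (0.11 ± 0.01, Tnnt3 0.18 ± 0.02) also stood apart with 0 genes called, but not with median centring (0.066 and 0.053) nor on either array alone.

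Purine breakdown and salvage (-0.02 ± 0.01, 2 of 20 called lower), de novo purine synthesis (-0.04 ± 0.06, 0 called) and pyrimidine metabolism (0.01 ± 0.02, 5 of 20 called lower) did not stand apart in spleen, but pyrimidine metabolism did without the genes of the other tissue (0.093, 11 of 14 above 0, 0 called). The Uox ratio was -6.82 ± 0.76 and was called lower, while Xdh (-0.51 ± 0.18), Slc29a1 (-0.49 ± 0.06), Cad (0.12 ± 0.06) and Ppat (-0.04 ± 0.09) were not called. The Uox value lay near those of hepatocyte genes such as Rbp4 (-6.65) and Fgb (-6.17). In low-NP spleen, 4 pyrimidine genes at least 16-fold higher in NP liver had median shares of the liver signal between 18.9% and 26.5%. The calls in these lists thus do not separate spleen metabolism from liver RNA in the pool. Nucleases and nucleic acid sensors (0.03 ± 0.02, 5 of 24 lower), amino acid stress (-0.06 ± 0.03, 5 of 18 lower, Atf5 at -1.64 ± 0.07), cytokines (0.03 ± 0.05, 0 called), adipocytes (-0.14 ± 0.06, 3 of 13 lower, Pck1 at -6.17 ± 0.12) and immediate early genes (-0.01 ± 0.02, 0 called) did not stand apart. Pck1 is also in the glucose production list, so its value is not particular to adipocytes. The ribosomal list, at 0.09 ± 0.43, had medians of opposite sign on the 2 arrays.

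Of the 1170 genes called lower in spleen, 1029 were at least 2-fold higher in the NP liver pool than in the low-NP spleen pool, which is 87.9%. At least 4-fold, the share was 60.3%, against 1.03% of the other measured genes. Without the genes at least 2-fold higher in the other tissue, 141 were called lower and 8 higher. The rule sets NP liver against the low-NP spleen pool itself, so it keeps liver genes that are abundant in that pool. Akr1c6 (-8.75) and Fabp1 (-8.41) were among the 141. The hepatocyte list (-6.17, 9 of 9 called lower), sex-biased liver genes (-4.89, 5 of 7) and the acute-phase list (-2.35, 5 of 8) still stood apart. Plasma cells (-0.19) did too, with Fkbp11 (-1.09) the 1 of 14 genes called lower. Glucose production (0.066), the circadian clock (0.085), oxidative stress (-0.035), bile duct (-0.10) and dendritic cells (0.08) then did not stand apart, and too few genes were left for a median of cholesterol synthesis, bile acid synthesis and the urea cycle. The count of higher genes was 225 on array 1 alone and 50 on array 2 alone, 48 from the scanner software's processed signals and 3 with median centring.

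**Figure D3:**
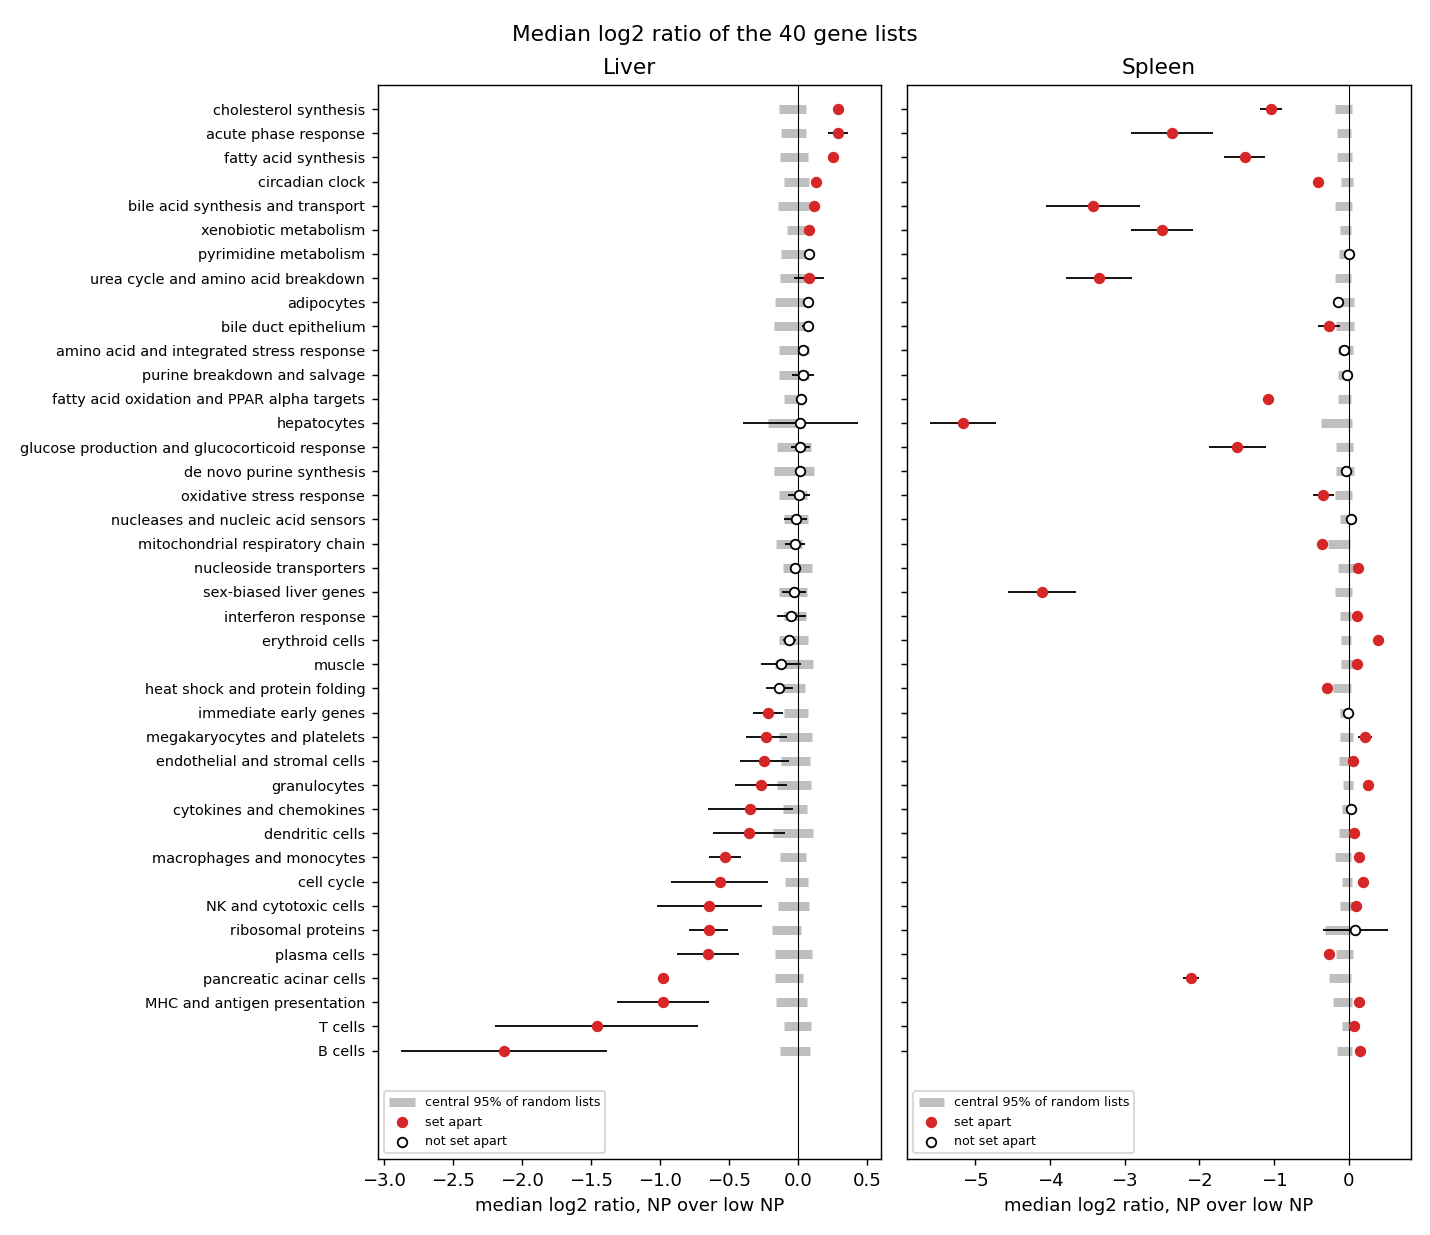
Median log2 ratio of NP over low NP (horizontal axes) of the 40 gene lists in liver and spleen, in the order of their liver medians, with red points for lists that stood apart, white for those that did not, black lines for the distance of the array medians from their own mean and grey bars for the central 95% of 10000 random lists matched on intensity. The B cell list was at -2.13 in liver and 0.16 in spleen (-0.11 with median centring, which also turned 9 other spleen lists below 0), and the hepatocyte list at 0.02 and -5.17.

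The tissues were then compared across the 16484 genes measured in both. Of the 28 genes called lower in both tissues, 20 were in the exocrine pancreas list, among them the trypsinogen gene Try5 (-1.48 ± 0.03 in liver and -2.45 ± 0.22 in spleen) and the lipase gene Pnlip (-1.17 ± 0.08 and -2.31 ± 0.30). The immunoglobulin gene Ighg1 was called lower in both as well (-1.55 ± 0.44 and -1.07 ± 0.03). Independent lists of the same sizes would share 43.9 genes called lower. No gene was called higher in both, 4 were called higher in liver and lower in spleen, and 1 was called lower in liver and higher in spleen. Across genes, which are not independent replicates, the log2 ratios of the tissues had a Pearson correlation of -0.19 and a Spearman correlation of -0.58. Between the dye orientations of one tissue the Pearson correlation was 0.70 in liver and 0.92 in spleen. The Spearman correlation between them was 0.34 in liver and 0.40 in spleen, smaller in size than that between the tissues. Without the genes that were at least 2-fold higher in the other tissue the correlation between the tissues was 0.047, and with median centring 4 genes in place of 28 were called in the same direction.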

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

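All tests in this part were chosen after the results were seen. The differences between liver and spleen were not tested, because the arrays of each tissue were treated as 1 pool per diet. The lists given here stood apart in both tissues and the genes were called in both, on opposite sides of 0 on every array. For lists, each value is the liver median minus the spleen median of log2 NP over low NP, and for genes the difference of the means.

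The medians of 5 metabolic lists, the circadian clock list and the acute-phase list lay above 0 in liver and below 0 in spleen. The difference was 1.33 for cholesterol synthesis, 1.65 for fatty acid synthesis, 3.54 for bile acid synthesis and transport, 2.58 for xenobiotic metabolism, 3.43 for urea cycle and amino acid breakdown, 0.55 for the circadian clock and 2.66 for the acute-phase response. Dilution of liver RNA in the low-NP liver pool was not tested for the metabolic and clock lists. Lists of immune cells, megakaryocytes, endothelial cells and the cell cycle had medians below 0 in liver and above 0 in spleen, where none of their genes was called higher and 4 endothelial, 2 macrophage and 1 T cell genes were called lower. The difference was -1.12 for antigen presentation, -2.28 for B cells, -1.54 for T cells, -0.74 for natural killer and cytotoxic cells, -0.66 for macrophages and monocytes, -0.53 for granulocytes, -0.43 for dendritic cells, -0.44 for megakaryocytes and platelets, -0.30 for endothelial and stromal cells and -0.76 for the cell cycle. Median centring turned the spleen medians of these lists below 0, except that of granulocytes (0.20). Without genes at least 2-fold higher in the other tissue, the liver medians of macrophages (0.025), granulocytes (0.11) and endothelial cells (0.14) and the spleen median of the circadian clock (0.085) lay above 0. The liver lists of T cells, dendritic cells, megakaryocytes and the cell cycle then did not stand apart. The genes Cyp7a1 (3.96), Saa1 (5.13), Saa2 (5.43) and Saa3 (4.04) were called higher in liver and lower in spleen.

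The lower lymphoid genes in NP liver were set against 3 explanations, of which RNA of a spleen like the 2 spleen pools would bring erythroid and granulocyte transcripts at the share of the lymphocyte genes. In the low-NP liver pool the share of 10 such genes was at most 17.8% of that of 23 B and T cell genes over the 4 estimates. However, Hba-a1 (-1.88 ± 0.13), Hbb-bt (-2.18, arrays -1.96 and -2.40) and S100a9 (-1.94 ± 0.21) were lower on NP. The globin genes were chosen after their values were seen. Hba-a1 lay below the 16-fold limit of the share estimate (14.6 in NP liver and 18.0 in NP spleen on the log2 scale). A lymphoid tissue poor in erythroid and granulocytic cells remains a candidate source, since in the lowest of the 4 estimates 85.3% of 218 genes at least 16-fold higher in NP spleen lay within 2-fold of one common share, with medians between 12.2% and 19.1%. That tissue could be spleen of another makeup, since the spleen genes Spic (11.8 on the log2 scale in low-NP liver, 9.74 in NP liver and 15.0 in NP spleen), Tlx1 (8.87, 7.95 and 10.6) and Nkx2-5 (8.40, 7.90 and 9.52), taken after their values were seen and the last 2 near background, were higher in low-NP than in NP liver. A difference between the diets in leukocytes of the liver stays open, because pooled RNA cannot separate it from the makeup of a pool.

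The lower hepatocyte genes in NP spleen were set against 3 explanations. Error following the dye was small, since the genes past 1.5-fold that followed the dye were 2.12% of those that followed the diet. Liver RNA in the low-NP spleen pool remains a candidate source, since in the lowest of the 4 estimates 75.9% of 573 genes at least 16-fold higher in NP liver lay within 2-fold of one common share, with medians between 15.6% and 23.5%. Part of the values lay apart from it, since 16 genes of the hepatocyte list, some saturated, had median shares between 34.4% and 49.3%. For 3 acute-phase genes called higher in NP liver the shares were 5.46% and 4.48% against the low-NP liver pool. Against the NP liver pool they were 0.574% and 1.20%, which the choice of genes high in that pool makes low. The upper quartiles of the 16 genes were 106% and 115% in the Cy3 estimates, above the full signal of the liver pools. In the Cy5 estimates they were 47.6% and 46.7%. A difference between the diets in the spleen itself was not tested and stays open with pooled RNA.

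The higher acute-phase genes in NP liver were set against 2 explanations. Dilution of hepatocyte RNA in the low-NP pool would raise hepatocyte genes alike. The median of the 5 called acute-phase genes exceeded that of the hepatocyte list by 2.63, more than the distance of the arrays from their means. These 5 genes were picked by the same values, so part of this excess comes from the choice. The whole acute-phase list was at 0.29 ± 0.07 and the hepatocyte list at 0.02 ± 0.42, which does not separate the lists. The values thus concern the 5 genes only. A few mice of the NP pool with an acute-phase reaction, and an effect of the diet, stay open, because pooled RNA gives no spread between mice.

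The E1A spike-in control probes, which the comparisons do not use, had correlated ratios of Cy5 over Cy3 on all 4 arrays, but not equal ones. Probe E1A_r60_1 was at -0.67 and -0.03 on the liver arrays and at 0.38 and 0.42 on the spleen arrays. The 10 probes ranged from -4.04 to 3.39 on the log2 scale, and the lowest correlation between arrays was 0.986.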

How the results depend on the processing

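The alternatives with negative controls as background and without genes of the other tissue were chosen after the data were seen. No paired analysis was possible because the results come from no test, and the numbers of the pooled samples go with the dye orientation in the labels. Signal over background limits dim genes. Every alternative that gave counts called more genes lower than higher in each tissue. Set against the reported values, single genes moved by less than the SD of the arrays in 4402 cases and by more in 671, and no called value changed sign. For list medians the numbers were 665 and 274, with 16 more changing sign. In 11 of the 12 genes called higher in liver and 612 of the 620 lower, the processed signals gave the same call. For the values below, the cause was not tested unless named.

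The scanner software's processed signals gave 297 liver genes higher and 1745 lower and 48 spleen genes higher, and the authors' deposited values gave 306, 1752 and 48. The processed signals put the median of all genes at 0.11 in liver and 0.10 in spleen. No background correction gave 1328 liver genes lower, negative controls as background 1354, and an offset of 0 gave 14 spleen genes higher. The 2-fold threshold gave 6 higher and 296 lower in liver, 1 and 772 in spleen and 9 in both, by its construction. The 1.3-fold threshold gave 49 and 1001 in liver and 45 higher in spleen, and the rule on the mean of the arrays gave 22, 1195 and 21. Median centring gave 324 liver genes lower, 3 spleen genes higher, 4 genes called in both tissues, a correlation of -0.26, and 12 lists apart in liver and 18 in spleen. With it the spleen medians fell below 0, together with that of all genes, for interferon response (-0.070), antigen presentation (-0.13), B cells (-0.11), T cells (-0.16), natural killer cells (-0.036), macrophages (-0.14), dendritic cells (-0.064), megakaryocytes (-0.024), endothelial genes (-0.16) and the cell cycle (-0.025). Leaving out genes of the other tissue gave 54 liver and 141 spleen genes lower by its construction, 13 liver lists apart and a correlation of 0.047. It left too few genes for a median of 5 lists that stood apart. The liver medians of cytokines (0.016), macrophages (0.025), granulocytes (0.11) and endothelial genes (0.14) and the spleen medians of glucose production (0.066) and the circadian clock (0.085) then lay above 0. With 1 array of each tissue left out, the counts ranged from 86 to 345 higher and 700 to 1941 lower in liver, from 50 to 225 higher and 1243 to 1673 lower in spleen and from 35 to 128 called the same way in both, with a correlation from -0.20 to -0.13. Of the lists that stood apart, 12 of 22 in liver and 14 of 31 in spleen lay outside the range of random lists under every alternative that gave a median.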

Other observations

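The genes named in this part were chosen after their values were seen. The Kupffer cell gene Clec4f was at 13.3 in low-NP liver and 13.4 in NP liver on the normalized log2 scale, and at 11.4 in low-NP spleen and, on arrays 1 and 2, 10.1 and 7.04 in NP spleen. Vsig4 went the same way, at 11.6 and 11.8 in low-NP and NP liver and 9.94 and 8.47 in low-NP and NP spleen. In the same order, Timd4 (10.5, 9.98, 11.9 and 12.0) and Cd5l (14.9, 14.8, 15.5 and 15.4) did not.

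After genes at least 2-fold higher in the other tissue were left out, 20 of the 54 genes called lower in liver and 24 of the 141 in spleen were in the exocrine pancreas list. The 141 also held the 9 genes of the hepatocyte list that were left. Prss2 was at 14.4 in low-NP liver and 13.2 in NP liver, and at 16.6 in low-NP spleen and 14.4 in NP spleen. The source of the pancreatic transcripts was not tested.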
